A study of Homo sapiens with 2 samples.

How the data were processed

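Total RNA of MCF7 cells, an established line of oestrogen receptor-positive breast cancer, was measured on 2 one-colour Agilent arrays for long non-coding and messenger RNA. One array held Cy3-labelled cRNA of the parental cells and the other that of tamoxifen-resistant MCF7 cells. Per the labels' protocols, parental cells were maintained with 10% serum and 0.01 mg/ml insulin. They were plated for 24 h and then kept for 48 h in phenol red-free medium with 5% charcoal-stripped serum. The resistant cells were maintained in the steroid-depleted medium and kept in it for 48 h before harvest. The maintenance medium therefore differed between the groups along with resistance, and the labels used here do not say whether tamoxifen was present. cRNA was made from 0.2 μg of RNA per sample.

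The scanner files hold spot intensity values deposited by the authors. Per the file headers, Agilent Feature Extraction subtracted the background, detrended the signals over the slide and flagged each spot as well above background, saturated or an outlier; the submitters' processing notes give its version as 10.7.1.1. No scaling between arrays was recorded for these intensity values. Both arrays lay on 1 slide with 1 scan, so slide and scan did not separate the groups. Each array held 155894 spots, of which 4974 were control spots by type, and the transcript probes took 150520 spots under 71508 probe IDs. A series table deposited by the authors holds log2 values for 71573 rows. Its resistant column equalled the mean log2 signal of each probe on the resistant array minus a constant of 9.69 in 99.6% of rows, within 0.0001. Its parental column did not follow the parental array by probe ID and was not used for any comparison. The medians of the columns were −2.65 in the parental and −2.77 in the resistant column.

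The files list every probe as unmapped, with no gene name, accession or position, and the reference tables (human gene symbols, assembly GRCh38.p14) do not pair such IDs with genes. Gene symbols occur only in the IDs of probes for the HOX loci and in control probes for GAPDH and PGK1. Of the 34 gene lists fixed before the data were examined, 1 could be measured, the list of HOX genes. The other lists had fewer than 5 members nameable from probe IDs, the minimum set, and are not reported. Those of oestrogen receptor targets, luminal, basal, mesenchymal and proliferation genes are among them. Probe sequences were not aligned to a genome to name further members. The rule for named genes (the largest differences each way, members of fixed lists past the size rule, and 16 genes always named) could be applied to HOX genes only, so at most 2 probe IDs without a gene are named in each direction. These were the largest difference among IDs starting with CB_ and among all other IDs, called catalogue IDs here. Spots of each had to agree within 1 log2 unit, a condition set after the values were seen. The files do not explain the ID prefixes, and CB_ was not read as messenger RNA.

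Identical sequences under different IDs were treated as 1 probe, a choice made after the data were examined, because 8312 IDs shared 3285 sequences. Signals were taken as log2 of the processed signal minus the 75th percentile of the array's non-control spots, which was 711 for the parental and 787 for the resistant array. Spots flagged as outliers on either array were left out (316 and 369 spots were flagged). No spot was saturated. All remaining spots of a sequence were averaged, and a sequence counted as measured when a share of at least 0.5 of its spots was well above background on each array. A difference is resistant minus parental on the log2 scale, and a sequence was called higher or lower when it differed by at least 2-fold with all its spots in the same direction. For a HOX gene the value was the mean over its measured sequences with the ID prefix hox, and all of these had to agree in sign. Where a sequence was well above background on every spot of one array and on none of the other, the fold is a lower bound against the higher of the dim array's lowest signal well above background and the dim sequence's own signal.

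With 1 array per group there is no replicate, so no test across conditions was run and no p-value is given; the number of arrays limits the precision. The error given with a difference is the SD between spots, which is technical, or the scanner software's own error carried to the log2 scale, with a median of 0.20. To describe whether a set of sequences stood apart, its median was ranked among the medians of 10000 random sets of the same size drawn from measured sequences in 20 bins of signal. Probes of one locus are not independent, so this rank describes these arrays only. Intervals of medians are 95% intervals from resampling the sequences. They treat probes of one locus as independent and leave out variation between cultures and arrays, so they may be too narrow. The steps were tested on simulated data over 47586 sequences: of 50 sequences raised by 1.3 on the log2 scale 94% were called, of 50 lowered by 1.3 98%, and of those changed by 2 in either direction all were. The smaller size was changed after a first run, because its former, slightly smaller value was the same as a measured difference in the report; at that size slightly fewer sequences were called. Among the 47386 others, which carried spot noise and a small spread, 0.893% were called. The changed sequences carried spot noise only, drawn without regard to signal. The SD of all measured differences on the real arrays was 0.74, so these shares describe the steps and not the data. A simulated list of 40 members raised by 0.5 ranked above all random sets, and an unmoved one at the 67.4th percentile.

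Alternatives fixed before the data were examined were median scaling, the 75th percentile over measured sequences, quantile and cyclic loess normalization, normexp background correction with an offset of 50, other filters on dim probes, other rules for probes of a gene, thresholds of 1.5-fold and 4-fold, kept outlier spots, detrending over rows and columns, another detection flag, and other bins for the random sets. Alternatives added afterwards were scaling on 8 E1A spike-ins, each probe ID or each group of sequences sharing 24 bases as the unit, subtraction of the median of sequences of like GC content and signal, and leaving out very bright HOX sequences. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, quantile and loess normalization.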

Results

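Transcript levels were compared between parental and tamoxifen-resistant MCF7 breast cancer cells, with 1 array per group and no replicates. The comparison asks which transcripts differ in cells that have become resistant to tamoxifen, an antagonist of the oestrogen receptor in breast tissue. Of 66480 distinct probe sequences, 47586 (71.6%) were measured on both arrays. Spots well above background made up 73.1% of transcript spots on the parental array and 73.4% on the resistant array, against 0.667% and 1.17% of 600 negative control spots. All differences are given as resistant minus parental on the log2 scale, and no difference has a replicate check.

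HOX genes, which encode transcription factors that set positional identity and lie in 4 clusters, were the gene family whose probes could be named. Probes carrying a HOXC gene in their ID were lower in resistant cells, and those carrying a HOXD gene were higher. The probes were not aligned to a genome, so whether each measures the gene in its ID was not tested. Of 58 measured HOXC sequences 55 lay below 0, with a median difference of −0.71 (95% interval −0.93 to −0.53). Of 30 measured HOXD sequences 28 lay above 0, with a median of 0.63 (interval 0.51 to 0.82). This median was 0.36 after normexp background correction and 0.0087 among the 7 HOXD sequences above the median signal of all sequences. The HOXC median lay below and the HOXD median above those of all 10000 random sets of like signal, whose middle 95% ran from −0.15 to 0.13 and from −0.24 to 0.16. The split by locus was made after the values were seen. Under every scaling tried the HOXC median stayed below 0 and the HOXD median above 0. Scaling on spike-ins, which moved the median of all sequences up by 0.41, gave −0.31 and 1.04.

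Across the HOXC locus, 20 sequences were at least 2-fold lower and none was at least 2-fold higher. Spike-in scaling raises each value by 0.41, so fewer of the 20 then stay 2-fold lower. The largest difference was that of a sequence named for HOXC11 with the ID prefix nc, at −2.34 ± 0.14 (SD between 2 spots), a 5.07-fold lower level. Its signal in resistant cells was −4.97 relative to the array's 75th percentile. Among sequences with the prefix hox, one of HOXC10 differed by −1.26 ± 0.22 (2.40-fold lower) and the brightest of HOXC9 by −1.25 ± 0.03 (2.38-fold lower). Another sequence named for HOXC9 differed by −1.05 ± 0.10. Other probes of the same genes differed less, by −0.39 for HOXC10 and −0.14 for HOXC9, so neither gene's mean passed 2-fold (−0.83 and −0.81). The HOXC9 sequence at −0.14 shares 52 bases on the opposite strand with a HOXC6 sequence, so which gene it measures was not tested. Both other measured HOXC9 sequences with the prefix hox passed 2-fold, so the gene's place below 2-fold rests on that sequence. Both HOXC8 sequences lay at −0.79 and −0.77, and the only measured HOXC6 sequence with this prefix went the other way, at 0.10. A further HOXC6 sequence with this prefix was well above background in parental cells only and at least 1.44-fold lower in resistant cells, so that the mean of both HOXC6 sequences was −0.92 with no filter on dim probes. The 44 sequences with the prefix nc had a median of −0.79, with 17 of them at least 2-fold lower, and the 11 with the prefix hox a median of −0.42, with 3 lower. By the gene in the ID, with all prefixes pooled, medians were −1.10 for 8 HOXC11 sequences and −0.75 for 11 of HOXC10. They were −0.88 for 8 of HOXC9, −0.85 for 9 of HOXC8, −0.59 for 15 of HOXC6 and −0.30 for 4 of HOXC5. Most HOXC sequences carry the prefix nc, so these medians can differ from the values of the prefix hox. The only measured HOXC11 sequence with the prefix hox differed by −0.42 and the only one of HOXC5 by −0.15.

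Across the HOXD locus, 7 sequences were at least 2-fold higher and 0 at least 2-fold lower. With spike-in scaling, which raises each value by 0.41, more HOXD sequences pass 2-fold higher. A HOXD4 sequence with the prefix hox differed by 1.41 ± 0.19 (2.66-fold higher), a HOXD9 sequence by 1.18 ± 0.26 (2.27-fold) and a HOXD10 sequence by 1.16 ± 0.14 (2.24-fold). Another HOXD4 sequence with this prefix differed by 0.53, so the gene's mean, 0.97, did not pass 2-fold. HOXD8 lay at 0.64 and 0.63 in its 2 sequences and HOXD3 at 0.37 and 0.26. The HOXD9 sequence was dim, at −5.83 in parental cells. After normexp background correction, whose offset shrinks dim differences by construction, its difference was 0.19 and that of HOXD10 was 0.90. A further sequence named for HOXD11 was well above background in resistant cells only and at least 2.51-fold higher there. The only HOXD13 sequence, one of the bright ones at a signal of 6.34, differed by 0.01. A sequence named for HOXD4 with the prefix nc had the largest value of the locus, 2.44, but its spots disagreed (SD 2.55).

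The other HOX loci differed less in the main setting. The HOXB median was 0.15 over 71 sequences (interval 0.06 to 0.24, at the 99.5th percentile of random sets), with 1 sequence, of HOXB6, past 2-fold at 1.05 ± 0.30; among the 16 HOXB sequences above the median signal of all sequences it was −0.010. The HOXA median was −0.07 over 18 sequences, at the 43rd percentile, and none passed 2-fold. Of the 57 HOXA sequences, 39 were not measured on both arrays. Under spike-in scaling the medians were 0.55 for HOXB and 0.33 for HOXA, both larger in size than the −0.31 of HOXC. Taken as the list of HOX genes fixed before the data were examined, 29 of its 39 genes were measured. HOXD9 and HOXD10 were at least 2-fold higher, 0 genes were at least 2-fold lower and 27 lay between; under some alternatives HOXC9 and HOXC10 passed 2-fold lower, HOXD4 and HOXD8 passed 2-fold higher, and HOXD9 and HOXD10 fell short. The median of the list was 0.10, at the 88.9th percentile of random sets.

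**Figure D1:**
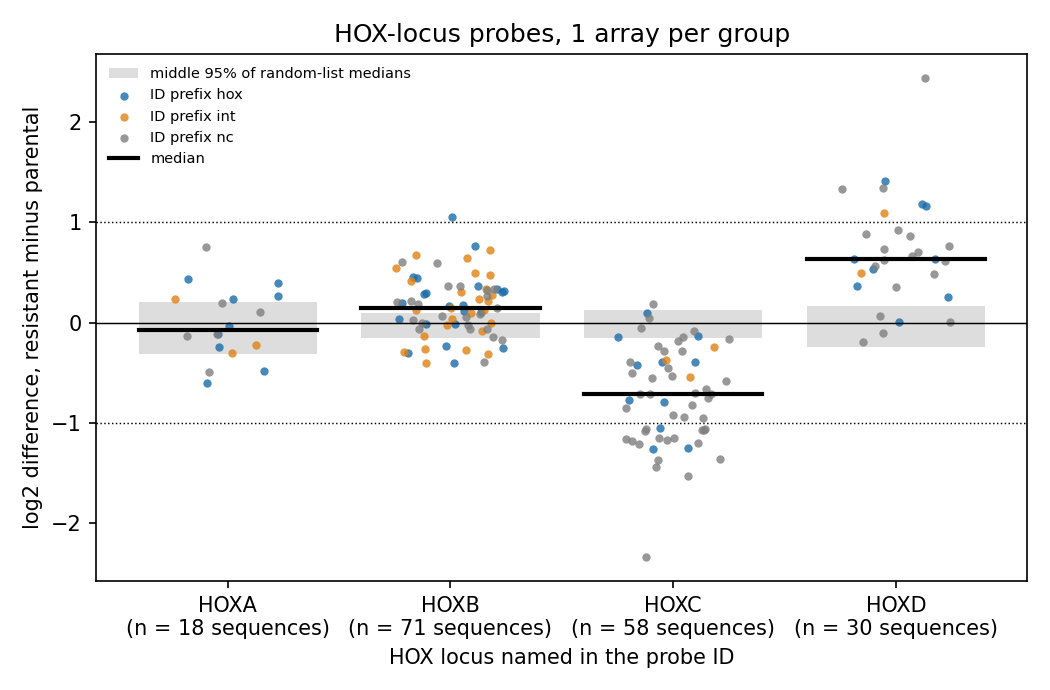
Log2 differences (resistant minus parental) of the measured HOX-locus sequences by locus, coloured by the prefix of the probe ID, with the median as a black line, the middle 95% of random-set medians as a grey band and dotted lines at 2-fold. HOXC sequences centre on −0.71 and HOXD sequences on 0.63, directions kept under every scaling tried although HOXD sequences above the median signal centre on 0.0087, while HOXA centres on −0.07.

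The reference transcripts GAPDH and PGK1, which encode enzymes of glycolysis, did not pass 2-fold. GAPDH differed by 0.42 at its 3′ probe and 0.24 at its 5′ probe, and PGK1 by 0.44 and 0.41, each as the mean of 10 spots. The middle 50% of all measured sequences lay between −0.31 and 0.30, with an SD of 0.74. Scaling each array on its median, on measured sequences or on spike-ins gave values from 0.21 to 0.84. The ratio of 3′ to 5′ signal, which reflects RNA integrity and labelling, differed between the arrays by 0.17 for GAPDH and 0.02 for PGK1 on the log2 scale.

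Over all measured sequences, 1619 (3.40%) were at least 2-fold higher and 2991 (6.29%) at least 2-fold lower in resistant cells. The median difference was 0.00 and the SD of differences 0.74. Lower sequences made up 64.9% of those called, against 54.7% after median scaling and 24.4% after spike-in scaling. At 4-fold, 232 were higher and 884 lower; this split was 464 and 561 after spike-in scaling. Sequences with CB_ IDs and catalogue sequences gave like shares. Of 25908 measured CB_ sequences 899 (3.47%) were higher and 1634 (6.31%) lower, and of 21678 catalogue sequences 720 (3.32%) were higher and 1357 (6.26%) lower. Over the 2 spots of a sequence, the SD of the resistant minus parental difference had a median of 0.08 and a 95th percentile of 0.50. This spread between spots leaves out variation of cultures, labelling and hybridization. On each array 37 sequences had spots more than 16-fold apart.

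**Figure D2:**
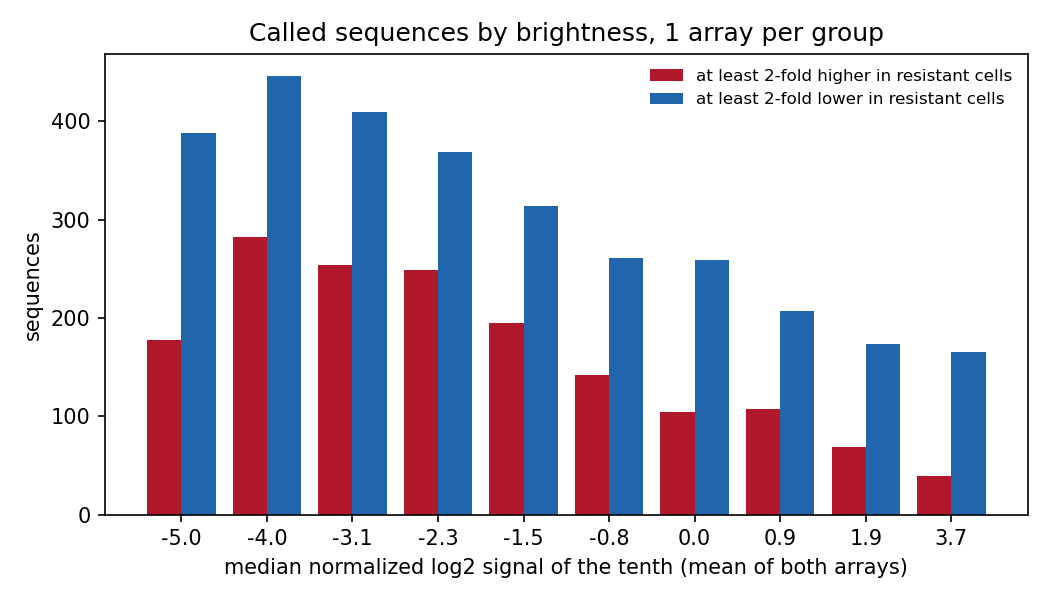
Number of sequences at least 2-fold higher (red) or lower (blue) in resistant cells, in 10 equal bins of all measured sequences ordered by signal, labelled by the median log2 signal of each bin. Lower sequences outnumbered higher ones in every bin, from 388 against 178 in the dimmest to 165 against 39 in the brightest; scaling on spike-ins turned the overall split.

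Among sequences measured on both arrays whose spots agreed within 1 log2 unit, the one lower by the most with a CB_ ID was CB_011513, whose sequence is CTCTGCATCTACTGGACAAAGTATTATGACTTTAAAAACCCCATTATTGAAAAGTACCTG. Some CB_ sequences detected on the parental array only were lower by more. CB_011513 differed by −8.77 ± 0.23 (SD between 2 spots), from 4.16 in parental to −4.61 in resistant cells. Among catalogue IDs, UCSC_11747_210, with the sequence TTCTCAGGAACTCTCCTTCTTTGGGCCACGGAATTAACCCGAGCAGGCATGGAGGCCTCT, was lower by the most, at −8.25 ± 0.13. Among the same sequences, the largest difference in the other direction was that of CB_011565, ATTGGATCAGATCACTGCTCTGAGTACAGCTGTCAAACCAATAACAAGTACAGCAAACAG, at 6.63 ± 0.23. It went from −5.57, near background, to 1.06. Among catalogue IDs the largest was that of UCSC_10378_699, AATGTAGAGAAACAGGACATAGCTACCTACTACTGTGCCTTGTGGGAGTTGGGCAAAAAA, at 6.01 ± 0.01. It overlaps other probes, and all 3 sequences of its overlap group were higher, by 5.80 to 6.01. Among 277 groups of at least 3 measured overlapping sequences, 6 were higher and 14 lower by at least 2-fold in every member, and 0 held members called in opposite directions.

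One sequence, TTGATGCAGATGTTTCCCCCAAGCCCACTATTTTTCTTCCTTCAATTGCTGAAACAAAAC, was spotted under 196 probe IDs, all with the prefix H-InvDB. It was higher in resistant cells, with a difference of 4.25 ± 0.08 (SD over 392 spots). Counted by ID, 234 H-InvDB probes were at least 2-fold higher and 168 lower; counted by sequence, 32 were higher and 144 lower.

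Sequences detected on 1 array only were about as frequent in both directions. On every spot of the resistant array and no spot of the parental array, 814 were well above background, and 226 of these were at least 2-fold higher by the lower bound. The reverse held for 895, of which 557 were at least 2-fold lower in resistant cells and 85 at least 16-fold lower, against 12 at least 16-fold higher. The largest bound was an at least 1808-fold lower level in resistant cells, and the largest in the other direction an at least 60.8-fold higher level.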

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

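Among the tests below, that of spike-in and other single scaling factors and that of the parental array's own values were chosen after the results were seen, and GC and signal subtraction, overlap groups and leaving out bright HOX sequences were added after the data were seen.

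Some probes of added or non-human control sequences, which lay outside the comparisons, gave signal well above background on every spot of both arrays. On the resistant array, log2 signal above the negative controls was 6.92 for ERCC-00012_90 and 5.33 for ERCC-00043_129, over 60 spots each, while the other 10 ERCC probes stayed at or near background. It was 4.28 for Mouse-GAPDH_3, 4.75 for Mouse-GAPDH_5 and 8.64 for Mouse-PGK1_5. Control spots were not filtered for outliers, and the 10 resistant spots of Mouse-PGK1_5 had an SD of 2.17, against 0.08 on the parental array. The rat probes gave 4.92 for Rat-GAPDH_3, 11.98 for Rat-GAPDH_5 and 10.08 for Rat-PGK1_5. The human GAPDH probes gave 14.24 and 14.49. Mouse-PGK1_3 was well above background on 0 of 10 parental and 2 of 10 resistant spots and Rat-PGK1_3 on 0 of either array. Among the E1A spike-ins, (+)E1A_r60_3 was so on 7 and 9 of 60 spots and (+)E1A_r60_a104 on 22 and 35.

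The opposite directions of the HOXC and HOXD loci formed the first pattern, with a gap between their medians of 1.35. Once the median of sequences of like GC content and signal was subtracted, the gap was 1.29 (95% interval 0.98 to 1.54), which argues against base composition or brightness as the whole cause. Under the lower of cyclic loess and quantile normalization it was 1.40 (1.12 to 1.66), which argues against a brightness-dependent trend over all sequences as the whole cause. The gap fell to 0.92 with normexp background correction and to 0.72 among sequences above the median signal, close to the 0.67 below which the pattern was not to count as kept. The 7 HOXD sequences above the median signal had a median of 0.0087, so an effect confined to dim probes stays open for the HOXD locus. That median is the value of the very bright HOXD13 sequence; with HOX sequences of log2 signal above 5 left out, the HOXD median was 0.66 and the gap 1.38. None of these sequences shared 24 bases on the same strand, so counting overlap groups once left all 58 and 30 values and the gap of 1.35 as they were and tests nothing; several probes of 1 transcript remain possible. On opposite strands, the HOXC6 sequence at 0.10 and the HOXC9 sequence at −0.14 share 52 bases, so these 2 values are not from separate sites. Resistance, the different maintenance medium and chance divergence of cultures stay open and untested, with 1 array per group.

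The excess of lower over higher sequences was the second pattern. Cyclic loess and quantile normalization left a share of lower sequences of at least 57.6%, which argues against a brightness-dependent trend as the whole cause. With spike-in scaling the share was 24.4%, so the excess at 2-fold may come from the choice of one scaling factor per array. Spike-ins were lower on the resistant array by a median of 0.26 before scaling, whereas its 75th percentile was higher by 0.15. At 16-fold the lower sequences outnumbered the higher ones under each single factor, by 102 to 60 with spike-ins and 146 to 38 in the main setting. A different total amount of transcript per unit of RNA between the cell groups was not tested.

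The parental column of the authors' value table was the third pattern: by probe ID its correlation across probes with the parental array was 0.0058, against 0.99997 for the resistant column with its own array, and 0.972 between both arrays. After adding 1 constant, 99.5% of its values equalled a probe mean of the parental array within 2e-06, where 3.75% would be found by chance, but only 0.0629% did so in their own row (within 0.0001). Of the same values 2.05% were found on the resistant array, which argues against another array's values. These values are consistent with the parental array's own data placed on other probe IDs. Read row by row, 84.8% of measured rows of that table lie at least 2-fold apart, against 10.4% on the arrays.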

How the results depend on the processing

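Scaling on spike-ins, choices of unit, GC subtraction and leaving out bright HOX sequences were added after the data were seen. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. No spot was saturated, both arrays share 1 slide, and the authors' table could not be used by row, so the alternatives on these points gave no values.

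Counts of higher and lower sequences (1619 and 2991; catalogue 720 and 1357) moved by over 1.5 times in 7 of 19 settings, or 6 of 19 for all lower sequences. Normexp gave 665 and 1778 (catalogue 236 and 721). No filter on dim probes gave 2795 and 5176 (1461 and 2627). Sequences above the median signal alone gave 461 and 1065 (149 and 396), by its construction. At 1.5-fold there were 5235 and 6492 (2253 and 3026), and at 4-fold 232 and 884 (87 and 377). Detection by gIsPosAndSignif gave 2494 higher sequences (1281 catalogue) and 2205 lower catalogue sequences. Spike-in scaling gave 5174 and 1674 (2241 and 720). The share of lower among called sequences, 64.9%, was 54.7% with median scaling and 79.2% at 4-fold, and turned to 24.4% with spike-ins. Counts of sequences detected on 1 array only were recomputed under 2 settings, kept outlier spots and gIsPosAndSignif, and stayed within 1.5 times.

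The HOXC median ran from −0.75 to −0.31 over 18 alternatives and the HOXD median from 0.0087 to 1.04. Spike-in scaling gave 0.33 for HOXA, 0.55 for HOXB, −0.31 for HOXC, 1.04 for HOXD and 0.51 for the HOX gene list. Normexp gave 0.047 for HOXB, 0.36 for HOXD and a HOXD minus HOXC gap of 0.92. Sequences above the median signal gave −0.010 for HOXB, 0.0087 for HOXD and a gap of 0.72. Median scaling gave 0.25 for HOXB and moved the median of all sequences by 0.10. Of 470 values of single HOX genes under alternatives, 14 crossed 2-fold. A change of sign was counted only for the genes past 2-fold, HOXD9 and HOXD10, and 0 values changed sign there. Smaller differences could turn, as that of HOXA1 from −0.03 to 0.37 with spike-in scaling. HOXC10 was −1.26 by its brightest probe or with all spots well above background. HOXC9 was −1.25 by its brightest probe, −1.05 by the median and −1.15 above the median signal. HOXD4 was 1.41 by its brightest probe, 1.07 with median scaling, 1.12 with quantile, 1.02 with loess and 1.38 with spike-in scaling, and HOXD8 1.04 with the last. HOXD10 fell to 0.90 with normexp and 0.92 with GC and signal subtraction, and HOXD9 to 0.19 with normexp. The normexp offset lowers such values by construction where the signal is dim. Apart from scaling and construction, the cause was not tested. Signal over background limits the dim probes, to which most HOX sequences belong.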

Other observations

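All observations here were chosen after the data were seen. Non-coding catalogues differed from each other by small amounts. The 50 measured sequences with the prefix lncRNAdb had a median difference of −0.19, at the 0.48th percentile of random sets of like signal, with 33 below 0. The 189 with the prefix CombinedLit lay at −0.14 (0.05th percentile), and shared 3 sequences with lncRNAdb, without which the medians were −0.14 and −0.15. The 271 with the prefix UCRs lay at 0.11, above all random sets of like signal and at the 98.4th percentile when GC content was matched too. Wherever GC content was matched here and below, signal was matched in fewer bins, so changes in rank may not come from GC content alone. The 241 with the prefix EvoFold, at 0.07, went from the 99.8th to the 87.5th percentile with GC content matched. Ranks of 2 other sets moved further. The 748 with the prefix imsncRNA, at −0.04, went from the 18.3rd to the 98.3rd percentile. The 830 with the prefix NRED, at −0.007, went from the 44.0th to the 0.75th. These sets are among 29 with at least 5 measured members. Spike-in scaling would move each median up by 0.41, which turns the lncRNAdb, CombinedLit, imsncRNA and NRED medians above 0. Prefixes of abundant structural RNAs had medians of −0.06 for 137 SRP_RNA sequences (16.7th percentile, or 10.9th with GC content matched), −0.13 for 25 of rRNA (7.5th, or 1.55th) and −0.09 for 82 of snRNA (7.9th, or 3.03rd); spike-in scaling turns these above 0 too.

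Sequence features that name a transcript class without a gene name were read from the probes. Of 29 measured sequences that encode TGEKP, the linker between zinc fingers of the C2H2 kind, 25 lay above 0, with a median of 0.21 at the 99.6th percentile of random sets, or the 96.5th with GC content matched; 0 passed 2-fold. The 75 sequences with the AU-rich nonamer TTATTTATT, an element of short-lived mRNAs, had a median of −0.13 at the 2.85th percentile, or the 0.44th with GC content matched, with 7 at least 2-fold lower and 1 higher. The 7 sequences with a histone stem-loop had a median of −0.14, at the 13.7th percentile, and 0 passed 2-fold. Spike-in scaling turns the medians of the AU-rich and stem-loop sets above 0.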
